A study of Mus musculus with 4 samples.

How the data were processed

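Cells of whole uteri on gestation day 3.5 were captured on the 10x Chromium 3′ platform per the labels, in 4 libraries, 2 per genotype, each from 2 pooled mice. The genotype of each library comes from the labels. The deposited matrices hold UMI counts per gene and barcode, made by the authors with Cell Ranger 6.0.0 per the file headers, on mm10 according to the submitters' processing notes. The authors also deposited an annotation of 44,040 barcodes that gives a quality status, 8 broad and 27 fine cell types. How it was made and how doublets were treated are not given in the sources used here. All count values were whole numbers, and the UMI and gene totals of each barcode were recomputed from the matrices. Barcodes that passed had at least 1000 genes and under 10% mitochondrial UMIs; 1130, 1022, 573 and 891 barcodes that met both limits failed on grounds not stated. Reads were not used here.

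Control 1 had 183,147,163 UMIs in all, control 2 259,724,755, knockout 1 189,273,536 and knockout 2 255,876,189. The libraries differ in depth within a genotype, with a median of 4078 and 5482 genes per passing cell in the controls and 4978 and 5627 in the knockouts. The error given with a level is the SD of 2 pooled libraries, which covers mice and capture together. Mice within a pool were not separated here.

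The UMIs of the 33,500 passing cells were summed by library and cell type. Broad types with at least 50 cells in each library (6 of 8) and fine types (11 of 27) were tested. Genes were filtered with filterByExpr, scaled with TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, as knockout against control, and p-values were adjusted by Benjamini-Hochberg within each cell type. Called means adjusted p under 0.05. CPM are TMM-scaled. Features that share a symbol (32) were kept apart by gene ID. Whether the genotype effect differed between 2 cell types was tested as an interaction with library as a block. A group at 0 counts is given as at least the ratio to a floor of 3 counts, and 1 to 3 counts as a ratio with a 95% counting interval that holds no replicate error.

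Gene lists of 13 functions and 15 cell types, with 449 symbols, were written before the data were examined. Each was tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with the correlation estimated from the libraries, and with fry. With 2 libraries per genotype that estimate rests on 2 residual degrees of freedom, so the test has little power to call a list. The list alone counts adjust p-values over the members of a list only. Genes named are Srf, Pgr, Esr1, Myocd, Mkl1 and Mkl2, and the 10 largest rises and falls of epithelium, fibroblasts and smooth muscle (3 and 3 in the other types). These had to be called, with both knockout libraries on one side of both controls and a mean of at least 10 CPM, leaving out predicted genes and those of mitochondria, ribosomal proteins and haemoglobin. Up to 4 members of each called list with the smallest p, and up to 2 called members of each other list, were added. Some genes that met the rule are not reported here. A few genes beyond it are given as not passing or as members of opposite sign.

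Cell numbers were tested with edgeR on counts per type against all passing cells, and shares also with an exact permutation test. Shares of cells with a UMI of Srf, Pgr, Mki67 or Top2a were taken with every cell thinned to 3000 UMIs (cells with fewer left out), and again at 1500 and unthinned. Limits on shares of 0 are Clopper-Pearson and hold counting error only. The share of RNA from other cell types in a sum was estimated from the marker genes of those types. The computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, with a seed of 1.

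The method was tested on counts simulated from the mean and dispersion that edgeR fitted to each gene. Among genes of at least 10 CPM, 100 were shifted by each of 2 known sizes. A log2 shift of 1 was recovered in 81% of genes in epithelium, 95% in fibroblasts, 69% in smooth muscle, 83% in perivascular, 86% in endothelial and 71% in immune cells, and a shift of 2 in 100% of each, with 13 to 24 false calls. For the interaction 164 of 200 were recovered with 16 false calls.

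Alternatives were median ratio size factors, library totals, leaving out each library in turn, a block on replicate number, DESeq2 1.42.0, no expression filter, cells of 1000 to 40,000 UMIs and at most 10% mitochondrial, and equal cell numbers thinned to 3000 UMIs. For smooth muscle this left 99 cells per library, and for epithelium 357. Others left out the 3558 cells above the 95th percentile of markers of another main type, took every barcode, weighted cell types alike, or took cell shares outside the immune types. Fits in glandular, luminal, stromal or basal cells alone, a fit without proliferating and unclassified epithelium, and Mki67 alone were added after results were seen. Pairing is unknown: deviations of replicates from genotype means correlated at −0.08 to 0.05, but depth followed replicate number. The 10,540 failing barcodes were left out of the tests, and no doublet caller was run.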

Results

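Single-cell RNA was sequenced from mouse uteri on gestation day 3.5, the day before the embryo attaches. Srf encodes serum response factor, a transcription factor that drives immediate early, actin and muscle genes. In the knockout, Cre recombinase made from the progesterone receptor locus (PgrCre/+) removes a loxP-flanked Srf gene (Srf flox/flox), so that cells of the progesterone receptor lineage lose it. Controls were Srf flox/flox mice without Cre, so Cre was present in knockouts only. Each genotype had 2 libraries, each made from 2 pooled mice, or 4 mice per genotype. The comparison asks what the loss of Srf does to each uterine cell type when the uterus becomes receptive.

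The deposited matrices held UMI counts of 30,828 features in 44,040 barcodes. The authors' annotation passed 33,500 barcodes, 9670 and 7931 in the controls and 8057 and 7842 in the knockouts. Their median depth was 14,326 and 25,012 UMIs per cell in the controls and 20,065 and 25,838 in the knockouts. Their median mitochondrial share was 4.88% and 5.50% in the controls and 3.74% and 4.11% in the knockouts, so it moved with genotype. The annotation gave 8 broad cell types, of which 6 had at least 50 cells in every library and were tested: epithelium, fibroblasts, smooth muscle, perivascular, endothelial and immune cells. Levels are CPM, computed from the UMIs summed over the cells of a type, as mean ± SD of the libraries of a genotype (n = 2), and each named type had its own fit. In each gene called among those chosen for naming, both knockout libraries lay on the same side of both controls: 61 of 61 in epithelium, 63 of 63 in fibroblasts, 58 of 58 in smooth muscle, 7 of 7 in perivascular, 6 of 6 in endothelial and 6 of 6 in immune cells. This was a condition for choosing the largest rises and falls, so for those it is no evidence.

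Srf fell in the epithelium, fibroblasts, smooth muscle and perivascular cells, the types with the most progesterone receptor transcripts, and was not called in endothelial or immune cells. Pgr, the progesterone receptor gene that carries Cre, rose in the epithelium. Esr1, the oestrogen receptor gene, fell in the epithelium as a whole, though not in its luminal cells, and rose in smooth muscle. Myocd encodes myocardin, a partner of serum response factor in muscle, and rose in smooth muscle and fibroblasts.

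Srf (ENSMUSG00000015605, chromosome 17 of mm10, 46,548,329 to 46,556,175, minus strand) had 85.1 ± 11.5 CPM in control epithelium and 0.779 ± 0.211 CPM in the knockout, 107-fold lower (log2 −6.74, SE 0.23, adjusted p = 0.000178). In fibroblasts it went from 19.1 ± 1.45 to 0.598 ± 0.296 CPM, 30.8-fold lower (adjusted p = 0.000575). In smooth muscle 74.6 ± 7.71 CPM stood against 29.3 ± 2.75, 2.48-fold lower (adjusted p = 0.00541), a call lost without control 2 (adjusted p = 0.0835). Perivascular cells went from 32.9 ± 3.86 to 7.78 ± 3.04 CPM, 4.12-fold lower (adjusted p = 0.0156). The log2 change was −0.02 in endothelial cells (adjusted p = 0.947) and −0.06 in immune cells (adjusted p = 0.831). The log2 fall was smaller in fibroblasts than in epithelium by 1.68 units (interaction adjusted p = 0.0416). Srf began from a lower control level in fibroblasts and ended at a similar knockout level, so this difference does not show more Srf left there. In smooth muscle the log2 fall was smaller than in epithelium by 5.47 (adjusted p = 1.74e-05). The labels do not say which exon is removed, so the 3′ tags counted may lie outside the deleted part.

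With each cell thinned to 3000 UMIs, the share of epithelial cells with a Srf UMI was 19.97% and 22.1% in the controls and 0.466% and 0.101% in the knockouts (8 of 1717 and 1 of 990 cells). In fibroblasts it was 5.49% and 5.44% against 0.137% and 0.419%, in smooth muscle 17.4% and 20.6% against 5.05% and 6.93%, and in perivascular cells 8.78% and 11.8% against 2.30% and 2.98%. Immune cells, outside the Pgr lineage, gave 6.50% and 8.25% against 5.36% and 6.60%. Without thinning the epithelial shares were 69.9%, 75.8%, 2.56% and 2.47%, at median depths of 18,568, 31,613, 29,292 and 38,320 UMIs. Thinning left out 42, 35, 40 and 23 epithelial cells for depth. The exact permutation test of 2 against 2 libraries cannot give a p below 0.33, the value it gave for Srf in each of these types except immune cells (exact permutation p = 0.667).

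Pgr (ENSMUSG00000031870, chromosome 9, 8,899,833 to 8,968,611, plus strand) rose 2.08-fold in the epithelium, from 102 ± 21.9 to 211 ± 19.1 CPM (adjusted p = 0.00998). It did not pass the test in fibroblasts (382 ± 8.98 against 403 ± 29.0 CPM, adjusted p = 0.616), smooth muscle (log2 0.43, adjusted p = 0.162), perivascular (0.19, adjusted p = 0.530), endothelial (−0.93, adjusted p = 0.0558) or immune cells (−0.25, adjusted p = 0.516). In endothelial cells it was called lower without control 1 (adjusted p = 0.00890), and in smooth muscle higher without knockout 1 (adjusted p = 0.0345). The thinned share of epithelial cells with a Pgr UMI was 20.1% and 30.3% in the controls and 40.8% and 46.3% in the knockouts. Immune cells, taken as background, held 1.79% and 3.07% against 1.75% and 1.56%, at median depths of 6504, 8961, 6890 and 9499 UMIs. Unthinned, the epithelial shares were 64.1%, 82.7%, 92.0% and 93.3% and the immune shares 4.55%, 6.71%, 4.25% and 5.19%. Thinning left out 111, 38, 294 and 80 immune cells. Esr1 was 1.85-fold lower in epithelium (1965 ± 174 against 1060 ± 124 CPM, adjusted p = 0.00994; adjusted p = 0.0584 without control 2). In luminal cells alone its log2 change was 0.43 and did not pass (adjusted p = 0.0869). It was 1.91-fold higher in smooth muscle (475 ± 47.5 against 910 ± 65.4 CPM, adjusted p = 0.00765), a call lost without control 1 (adjusted p = 0.0838) or control 2 (0.0835). Myocd was 2.10-fold higher in smooth muscle (adjusted p = 0.0425, lost without control 1 at 0.231, control 2 at 0.280 and knockout 2 at 0.0759). It was 5.82-fold higher in fibroblasts, at a low 0.303 ± 0.0694 against 1.74 ± 0.0949 CPM (adjusted p = 0.00232). The genes of the myocardin-related factors, Mkl1 and Mkl2 (also Mrtfa and Mrtfb), fell in fibroblasts, 1.48-fold (adjusted p = 0.00918; 0.0657 without knockout 1) and 2.08-fold (adjusted p = 0.00227). Neither passed in epithelium (adjusted p = 0.0805 and 0.348) or smooth muscle (0.749 and 0.788).

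**Figure D1:**
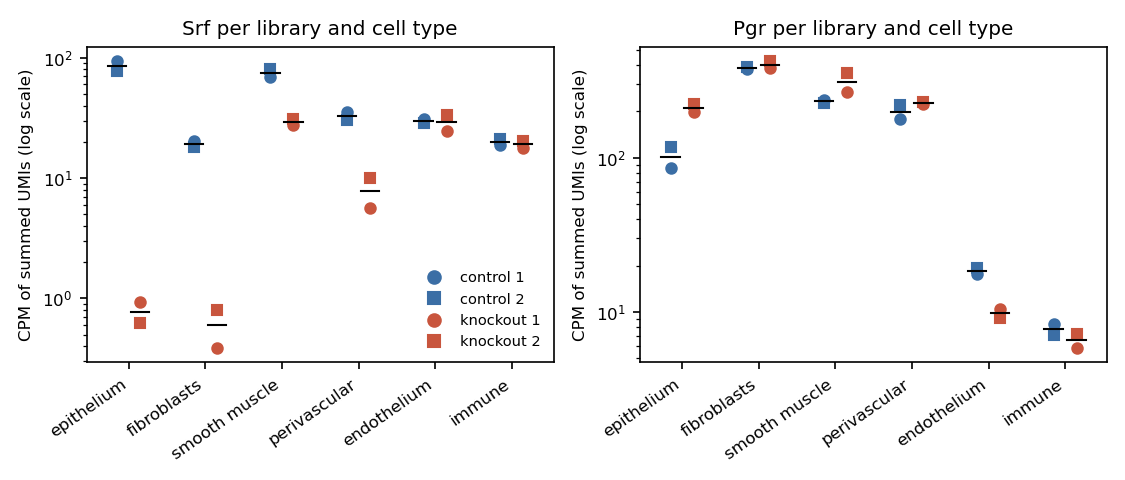
CPM of Srf and Pgr per library in the 6 tested cell types, on a log axis, with controls and knockouts side by side. Srf lies between 0.3 and 1 CPM in knockout epithelium and fibroblasts and near its control level in endothelial and immune cells.

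In the epithelium, genes of inflammation, cell division and oestrogen response were higher in the knockout, and immediate early, cytoskeletal and contractile genes were lower. As lists these calls did not hold with an estimated correlation (adjusted p = 0.308 to 0.428), and markers of muscle, pericytes and stroma fell with the contractile genes. Spp1, which encodes the adhesion protein osteopontin, rose, as did Lcn2, whose product binds iron carriers in acute inflammation. Spink1, a protease inhibitor secreted by uterine glands, fell, and so did Egr1 and Egr3, zinc-finger factors induced within minutes by growth factors. Isg15 and Bst2, induced by interferon against viruses, rose with every other tested member of their list.

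A total of 4110 of 14,947 genes passed in epithelium, 2102 higher and 2008 lower. The count was 2003 without control 1 and 2041 without knockout 2, and 2307 and 3748 without control 2 and knockout 1. With library totals in place of TMM the median log2 change of all genes moved from 0.01 to 0.16, and the split became 2922 higher and 1531 lower.

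Spp1 rose 234-fold in epithelium (0.963 ± 0.181 to 227 ± 28.6 CPM, adjusted p = 0.000141) and Lcn2 254-fold (2.99 ± 1.46 to 758 ± 352 CPM, adjusted p = 0.000980). The chemokine gene Cxcl5 rose 174-fold and the interleukin gene Il1f6 83.2-fold. Pbk and Cenpf, both active in mitosis, rose 76.6-fold and 72.8-fold, and Egfl6, which encodes a secreted growth factor-like protein, 68.7-fold (adjusted p = 0.000537 to 0.00158 for these 5). Sprr2b, an envelope protein gene of stressed epithelium, was at 0 counts in both controls and at 5527 in the knockouts, at least 515-fold higher against a floor of 3 counts over the group. Its paralog Sprr2d went from 1 count to 4198, a ratio of 1174 (95% counting interval 211 to 46,370). The Sprr2 genes are near-identical in sequence, so the assignment among them is uncertain. Wif1, a secreted Wnt inhibitor gene, went from 1 to 2074 counts (ratio 580, 104 to 22,914), with unequal knockout libraries (23.9 ± 23.4 CPM).

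Egr4, of the same family as Egr1, had 978 control counts and 0 knockout counts, at least 1166-fold lower. Egr3 was 229-fold lower (53.3 ± 18.4 to 0.227 ± 0.0131 CPM) and Egr1 41.7-fold lower (368 ± 49.8 to 8.81 ± 0.817 CPM, adjusted p = 0.000178). Spink1 fell 203-fold (945 ± 50.0 to 4.62 ± 1.33 CPM, adjusted p = 0.000178) and Calca, which encodes the progesterone-induced peptide calcitonin, 102-fold (65.4 ± 17.5 to 0.606 ± 0.481 CPM, adjusted p = 0.00114). The synaptic scaffold gene Lrrc7 fell 71.5-fold (440 ± 4.46 to 6.15 ± 0.278 CPM). Slc24a4, an ion exchanger gene, fell 93.4-fold, Thsd7b 73.0-fold, and the kinase gene Alpk1 47.0-fold, the last from unequal controls (166 ± 144 CPM).

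**Figure D2:**
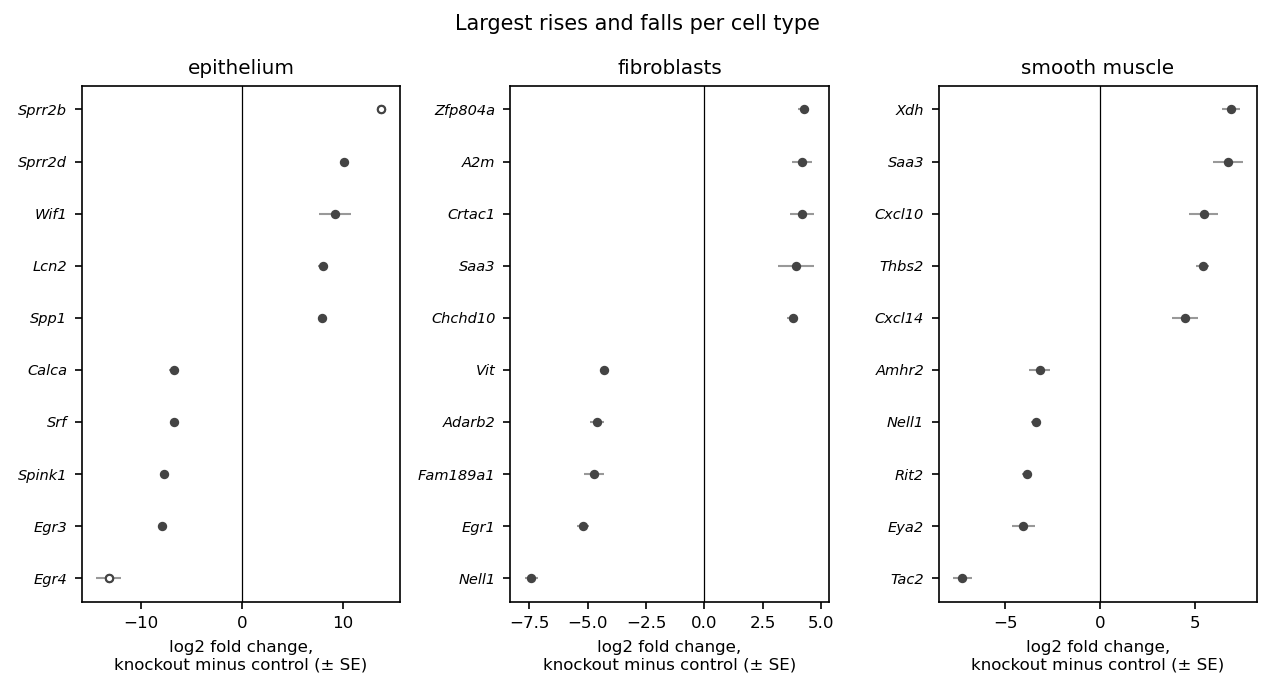
Log2 fold changes, knockout over control with SE, of the 5 largest rises and 5 largest falls in epithelium, fibroblasts and smooth muscle. Open symbols mark genes at 0 counts in one genotype, such as Sprr2b and Egr4, whose fitted value depends on the prior count.

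Of the 20 serum-response immediate early genes tested in epithelium, 15 fell and 0 rose (also 15 and 0 adjusted over the list alone; camera adjusted p = 3.09e-07, adjusted p = 0.414 with an estimated correlation). Egr2 fell 108-fold and Ier2 3.97-fold. Actin cytoskeleton and focal adhesion genes fell in 15 of 30 and rose in 2 (17 and 6 adjusted over the list alone; adjusted p = 0.000210, and adjusted p = 0.428 with an estimated correlation). The cytoplasmic actin gene Actg1 was 4.75-fold lower, Vcl, which links integrins to actin, 15.6-fold, Cnn2 13.6-fold and Itga5 2.87-fold.

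Smooth muscle contractile genes fell in 15 of the 23 tested in epithelium and rose in 1 (16 and 1 adjusted over the list alone; adjusted p = 8.72e-07, and adjusted p = 0.414 with an estimated correlation). Csrp1 fell 14.5-fold (516 ± 128 to 35.6 ± 1.92 CPM), Tpm1 6.63-fold, Synpo2 8.14-fold and Cald1 36.7-fold (209 ± 199 to 5.71 ± 0.207 CPM, unequal controls). Marker lists of other cell types fell in the epithelial sums as well: pericyte (8 of 10 lower, adjusted p = 0.000844), smooth muscle (5 of 8, adjusted p = 0.000844), blood endothelium (6 of 12, adjusted p = 0.00965) and stromal fibroblast markers (5 of 12 lower and 1 higher, adjusted p = 0.0158), each at adjusted p = 0.779 with an estimated correlation. The estimated share of fibroblast RNA in the epithelial sums was 1.67% and 1.49% in the controls and 0.595% and 0.863% in the knockouts. For the 12 fallen contractile genes under 50 CPM in the controls, RNA of 4 other cell types could supply a median of 120% of the difference, and for the 3 above it 1.91%. The first value rests on markers that include 3 of the 12 genes. Uterine contractility signalling genes fell in 9 of 19 and rose in 1 (9 and 1 adjusted over the list alone; adjusted p = 0.00141, and adjusted p = 0.308 with an estimated correlation). In luminal cells alone that list turned direction without passing (adjusted p = 0.157). The potassium channel gene Kcnma1 was 8.89-fold lower (in luminal cells alone log2 1.31, adjusted p = 0.181), the muscarinic receptor gene Chrm3 4.78-fold (but higher in luminal cells alone, log2 2.29) and the prostaglandin receptor gene Ptger4 3.28-fold. Cacna1c, 3.88-fold lower at 4.57 ± 0.123 CPM in the controls, had a log2 change of −0.03 (adjusted p = 0.953) without cells high in markers of other types.

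Progesterone-response genes fell in 10 of 23 and rose in 2 (14 and 3 adjusted over the list alone; adjusted p = 0.000740, and adjusted p = 0.308 with an estimated correlation). Beside Calca, the transcription factor gene Zbtb16 was 10.7-fold lower and the chaperone gene Fkbp5 2.62-fold, while Wnt4 was 5.87-fold higher at 15.5 ± 0.0543 CPM. Ihh, the hedgehog signal of the epithelium, had a log2 change of −0.10 and did not pass (adjusted p = 0.555). Implantation and decidualization genes fell in 9 of 21 and rose in 3 (10 and 3 adjusted over the list alone; adjusted p = 0.0261, and adjusted p = 0.335 with an estimated correlation), a call lost without knockout 1 (0.104) or knockout 2 (0.0721) and in glandular (0.0822) or luminal cells alone (0.907). Lif, the cytokine gene that implantation requires, was 6.58-fold lower (31.3 ± 14.8 to 4.74 ± 0.752 CPM, adjusted p = 0.00455) but higher in luminal cells alone (log2 3.14, adjusted p = 0.0283), its receptor subunit gene Il6st 2.67-fold lower, and the protease gene Mmp7 54.2-fold higher. Extracellular matrix genes fell in 13 of 30 and rose in 3 (14 and 4 adjusted over the list alone; adjusted p = 0.000163, and adjusted p = 0.436 with an estimated correlation; 0.12 in luminal cells alone). Thbs1 was 7.95-fold, Col4a1 8.68-fold and Timp3 9.19-fold lower, and Fbln1 7.21-fold higher. Members such as Dcn and Bgn are fibroblast genes, and since fibroblast RNA was a smaller part of the knockout epithelial sums, their fall is not assigned to epithelial cells; the supply from other types was not estimated for this list.

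All 20 interferon-stimulated genes tested rose in epithelium (20 adjusted over the list alone; adjusted p = 3.83e-13, and adjusted p = 0.308 with an estimated correlation). Ifi44 was 12.9-fold higher, Gbp2 10.6-fold, Isg15 9.58-fold and Bst2 4.04-fold. Cell cycle genes rose in 27 of 29 and fell in 0 (27 and 0 adjusted over the list alone; adjusted p = 6.02e-12, and adjusted p = 0.414 with an estimated correlation). The proliferation marker gene Mki67 rose 34.6-fold (2.57 ± 0.341 to 88.8 ± 36.1 CPM), Tpx2 32.0-fold and Nusap1 19.4-fold, while Top2a (log2 0.08, adjusted p = 0.680) and Tyms (0.35, adjusted p = 0.313) did not pass. The controls hardly had cells of the proliferating class. Without proliferating and unclassified epithelial cells the log2 change of Mki67 went from 5.11 to 2.39 (adjusted p = 0.0129), and the Nusap1 call was lost (0.57, adjusted p = 0.482). In luminal cells alone Mki67 did not pass (1.24, adjusted p = 0.134). Oestrogen-response genes rose in 13 of 18 and fell in 1 (13 and 1 adjusted over the list alone; adjusted p = 3.47e-06, and adjusted p = 0.308 with an estimated correlation). Beside Lcn2, the complement genes C3 and Cfb rose 29.1-fold and 17.9-fold and the chloride channel regulator gene Clca1 25.2-fold. Cytokine and acute inflammatory genes rose in 10 of 22 and fell in 1 (13 and 1 adjusted over the list alone; adjusted p = 0.000516, and adjusted p = 0.428 with an estimated correlation), among them Vcam1 29.9-fold and Cxcl10 12.8-fold. Neutrophil markers rose in the epithelial sums in 3 of 5 (adjusted p = 0.0158, and adjusted p = 0.779 with an estimated correlation).

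Neither dissociation stress and heat shock genes (6 of 20 higher and 3 lower, 6 and 6 adjusted over the list alone, adjusted p = 0.712) nor oxidative phosphorylation genes (0 of 28 higher and 1 lower, 0 and 0 adjusted over the list alone, 2 higher and 1 lower at an unadjusted p under 0.05, 0 and 1 with DESeq2, adjusted p = 0.624) passed as lists in epithelium. Atf3 was 3.30-fold lower, Hspb1 1.62-fold higher (lost without control 2, adjusted p = 0.109) and Cox4i1 1.45-fold lower (lost without control 1 at 0.175, control 2 at 0.106 and knockout 2 at 0.0708).

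The epithelium held glandular (489 and 269 control cells, 989 and 512 knockout cells) and luminal cells (145 and 73, 594 and 230). In luminal cells alone 8 of the named genes had the opposite sign, and 2 of these passed there: Lif was higher (log2 3.14, adjusted p = 0.0283) and so was Chrm3 (2.29, adjusted p = 0.0184). The other 6 were Atf3, Esr1, Hspb1, Il6st, Itga5 and Kcnma1. In glandular cells alone 0 of 55 called named genes changed sign, and 6 lost the call: Cacna1c, Cxcl10, Il1f6, Nusap1, Vcam1 and Wnt4 (adjusted p = 0.103 to 0.743).

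In fibroblasts, the stroma that will become the decidua, contractile and adhesion genes fell while interferon-stimulated, respiratory chain and cell cycle genes rose, list calls that did not hold with an estimated correlation (adjusted p = 0.525). Wnt4, a signal that promotes decidualization, and Cxcl14, a chemokine gene, rose. Egr1 fell here as in the epithelium, and so did Cnn2, a calponin gene that serum response factor regulates. Vit and Angptl7, which encode secreted matrix and angiopoietin-like proteins, fell as well.

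In fibroblasts 5101 of 17,420 genes passed, 2749 higher and 2352 lower. The count was 1340 without knockout 2, 2520 without knockout 1, 3239 without control 2 and 5534 without control 1. Library totals in place of TMM gave 3255 higher and 1903 lower. Among the largest rises, Zfp804a rose 18.9-fold (9.41 ± 1.5 to 177 ± 49.9 CPM), Wnt4 13.0-fold (7.41 ± 0.0605 to 96.3 ± 8.22 CPM, adjusted p = 9.09e-05) and Cxcl14 10.7-fold (43.7 ± 8.43 to 467 ± 61.8 CPM). The others were the protease inhibitor gene A2m (17.8-fold), Crtac1 (17.8), Saa3 (15.2, a gene with close paralogs; adjusted p = 0.0585 without knockout 1), Chchd10 (13.6), the receptor component gene Ramp3 (10.9), P2ry14 (10.6) and Syt1 (7.22). Nell1, which encodes a secreted glycoprotein, fell 169-fold (21.3 ± 4.39 to 0.131 ± 0.0423 CPM, adjusted p = 0.000148) and Egr1 36.6-fold (524 ± 149 to 14.3 ± 3.33 CPM). Vit fell 19.6-fold (206 ± 13.8 to 10.5 ± 1.33 CPM, adjusted p = 9.09e-05), Adarb2 24.1-fold, Fam189a1 26.3-fold, Cnn2 15.4-fold, Bmper 9.32-fold, Frmpd4 8.85-fold, Angptl7 8.82-fold and Nt5e 7.96-fold.

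Smooth muscle contractile genes fell in 17 of the 26 tested in fibroblasts and rose in 2 (19 and 2 adjusted over the list alone; adjusted p = 9.41e-08, and adjusted p = 0.525 with an estimated correlation). Tgfb1i1, a focal adhesion adaptor gene, was 6.34-fold lower, the myosin light chain gene Myl9 6.10-fold and Tpm2 4.31-fold. Smooth muscle markers fell in 5 of 11 and rose in 2, and that list did not pass (adjusted p = 0.389). The supply of muscle RNA to the fibroblast sums was not estimated. Actin cytoskeleton and focal adhesion genes fell in 13 of 29 and rose in 3 (14 and 5 adjusted over the list alone; adjusted p = 0.00142, and adjusted p = 0.525 with an estimated correlation), among them Actg1 5.92-fold, Fhl1 3.44-fold and Zyx 2.49-fold. Serum-response immediate early genes fell in 6 of 19 and rose in 0 (7 and 0 adjusted over the list alone; adjusted p = 0.00806, and adjusted p = 0.631 with an estimated correlation; adjusted p = 0.184 without control 1). Ier2 was 4.18-fold, Cyr61 5.72-fold and Btg2 3.56-fold lower.

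Interferon-stimulated genes rose in 16 of 20 and fell in 0 (18 and 0 adjusted over the list alone; adjusted p = 1.08e-08, and adjusted p = 0.525 with an estimated correlation), with Isg15 5.86-fold, Ifit3 4.61-fold, Rsad2 4.10-fold and Bst2 2.71-fold higher. Oxidative phosphorylation genes rose in 20 of 28 and fell in 0 (22 and 0 adjusted over the list alone; adjusted p = 7.44e-08, and adjusted p = 0.525 with an estimated correlation), with Uqcrq 2.45-fold, Cox5a 1.98-fold, Cox6c 1.91-fold and Atp5g1 1.91-fold higher. Cell cycle genes rose in 13 of 29 and fell in 0 (15 and 0 adjusted over the list alone; adjusted p = 7.44e-08, and adjusted p = 0.525 with an estimated correlation; 0.0867 in stromal fibroblasts alone). Among the 13 that rose were Ccne1 (3.69-fold), Hells (3.52), Mcm3 (3.03) and Mcm6 (2.15). Mki67 had a log2 change of −0.01 (adjusted p = 0.980).

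Cytokine and acute inflammatory genes rose in 6 of 23 and fell in 2 (6 and 2 adjusted over the list alone; adjusted p = 0.00141, and adjusted p = 0.536 with an estimated correlation; 0.0555 without control 2). Lcn2 was 133-fold and Cxcl5 48.7-fold higher, but at 3.84 ± 2.07 and 3.42 ± 2.33 CPM in knockout fibroblasts against 758 ± 352 and 97.4 ± 23.6 CPM in knockout epithelium, and Ccl8 was 4.5-fold higher. Oestrogen-response genes rose in 9 of 16 and fell in 2 (11 and 3 adjusted over the list alone; adjusted p = 0.0130, and adjusted p = 0.525 with an estimated correlation). Greb1 rose 3.11-fold (10.5 ± 3.00 to 32.8 ± 5.42 CPM), while Sprr2f (57.8-fold, uncertain among its paralogs) and Aqp8 (19.4-fold) stayed at 6.02 ± 3.39 and 1.31 ± 0.468 CPM in the knockout. Stress and heat shock genes rose in 9 of 20 and fell in 0 (10 and 0 adjusted over the list alone; adjusted p = 0.00259, and adjusted p = 0.536 with an estimated correlation; 0.0824 without control 2). Hmox1 was 2.50-fold, Hspd1 1.59-fold, Mt1 1.84-fold (lost without knockout 1, adjusted p = 0.0607) and Hspe1 1.45-fold higher (lost without knockout 1 at 0.0597 and knockout 2 at 0.0679).

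The other lists did not pass in fibroblasts. Progesterone-response genes fell in 6 of 24 and rose in 2 (7 and 2 adjusted over the list alone; adjusted p = 0.205), with Fst, an activin antagonist gene, 7.82-fold lower. Uterine contractility signalling genes fell in 7 of 25 and rose in 5 (7 and 5 adjusted over the list alone; adjusted p = 0.0593, and 0.0414 without control 1), with Ryr2 4.42-fold and Atp2b4 3.01-fold lower. Extracellular matrix genes rose in 9 of 30 and fell in 7 (11 and 8 adjusted over the list alone; adjusted p = 0.746), with Postn 5.44-fold and Fbn1 2.66-fold lower. Implantation and decidualization genes rose in 4 of 20 and fell in 3 (5 and 5 adjusted over the list alone; adjusted p = 0.635), with Alpl 4.03-fold higher and Spink1 65.4-fold lower from 2.19 ± 0.911 CPM. In the basal fibroblasts alone (373, 259, 97 and 275 cells), 25 of 52 named genes lost the call and 8 changed sign, 0 of these 8 passing there by edgeR (adjusted p = 0.129 to 0.990).

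In smooth muscle, the contractile genes that define the tissue fell and genes of matrix, inflammation and interferon response rose, list calls that did not hold with an estimated correlation (adjusted p = 0.172 to 0.230). Acta2, the actin of smooth muscle, and Tpm1, a tropomyosin, fell. Ptger3, a receptor through which prostaglandin E contracts the uterus, fell. Nfkbia, an NF-kappa B inhibitor, rose, as did the matrix genes Dcn and Fbln1, not assigned to muscle cells.

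In smooth muscle 968 of 12,304 genes passed, 491 higher and 477 lower, with only 105 cells in knockout 1. The count was 34 without control 2, 170 without control 1, 622 without knockout 2 and 1153 without knockout 1. With library totals the median log2 change moved from 0.01 to 0.13 and the split was 668 higher and 356 lower. Of the 58 named genes called, 46 lost the call when some library was left out, 45 without control 2, 24 without control 1, 14 without knockout 2 and 3 without knockout 1. The 12 that kept it were Dcn, Fbln1, Greb1, Me3, Nell1, Nfkbia, Ptger3, Rit2, Tac2, Tenm1, Thbs2 and Xdh. For the rest the adjusted p without control 2 ranged from 0.0502 (Acta2 and others) to 0.287 (Zbtb16), except Gja1, which lost its call without control 1 (0.0504) and knockout 2 (0.0592) only.

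Smooth muscle contractile genes fell in 20 of 26 and rose in 0 (24 and 0 adjusted over the list alone; adjusted p = 3.01e-22, and adjusted p = 0.230 with an estimated correlation). Acta2 was 2.23-fold lower (10,364 ± 8.06 to 4656 ± 173 CPM, adjusted p = 0.00236), Synm 3.43-fold, Hspb6 3.36-fold and Tpm1 2.20-fold. Smooth muscle markers (8 of 11 lower and 1 higher, adjusted p = 5.08e-08) and pericyte markers (2 of 7 lower, adjusted p = 0.00269) fell beside them, each at adjusted p = 0.671 with an estimated correlation. Actin cytoskeleton and focal adhesion genes fell in 11 of 29 and rose in 3 (15 and 3 adjusted over the list alone; adjusted p = 3.38e-06, and adjusted p = 0.243 with an estimated correlation), with Flna 2.42-fold, Cnn2 2.21-fold, Myl6 2.04-fold and Actb 1.71-fold lower. Uterine contractility signalling genes fell in 6 of 24 and rose in 2 (14 and 3 adjusted over the list alone; adjusted p = 2.16e-05, and adjusted p = 0.172 with an estimated correlation). Ptger3 was 4.07-fold lower (474 ± 45.4 to 118 ± 14.5 CPM, adjusted p = 0.00182), Pde5a 2.15-fold and Atp2b4 1.99-fold lower, and the gap junction gene Gja1 3.81-fold higher. Oxidative phosphorylation genes fell in 5 of 28 and rose in 0 (15 and 0 adjusted over the list alone; adjusted p = 6.82e-11, and adjusted p = 0.172 with an estimated correlation), with Ndufb8 1.55-fold, Ndufa4 1.53-fold, Atp5b 1.48-fold and Uqcrq 1.45-fold lower. Progesterone-response genes fell in 1 of 17 and rose in 0 (6 and 2 adjusted over the list alone; adjusted p = 0.0113, and adjusted p = 0.469 with an estimated correlation; 0.101 without knockout 1). Zbtb16 was 1.77-fold lower, and Hand2 (adjusted p = 0.0506), Ptch1 (0.0534) and Klf15 (0.0698) did not pass; without knockout 1 or knockout 2 the first pair passed, Hand2 at 0.0288 and 0.0149 and Ptch1 at 0.0156 and 0.00399.

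Extracellular matrix genes rose in 13 of 30 in smooth muscle and fell in 1 (16 and 2 adjusted over the list alone; adjusted p = 4.62e-07, and adjusted p = 0.172 with an estimated correlation). Fbln1 was 14.9-fold higher (3.66 ± 0.269 to 53.5 ± 5.73 CPM, adjusted p = 0.000546), the protease gene Mmp2 15.3-fold, Dcn 4.32-fold and Bgn 3.57-fold. Stromal fibroblast markers rose in 2 of 12 and did not pass as a list (adjusted p = 0.493). Cytokine and acute inflammatory genes rose in 9 of 14 and fell in 0 (12 and 0 adjusted over the list alone; adjusted p = 1.87e-08, and adjusted p = 0.230 with an estimated correlation), with Cxcl10 44.5-fold, Nfkbia 4.65-fold and Cxcl12 2.08-fold higher. Saa3, which has close paralogs, went from 2 counts to 205 (ratio 142, 38.8 to 1181). Interferon-stimulated genes rose in 9 of 17 and fell in 0 (14 and 0 adjusted over the list alone; adjusted p = 9.87e-11, and adjusted p = 0.230 with an estimated correlation), with Ifi44 8.5-fold, Ifit1 6.64-fold and Isg15 5.26-fold higher. Oestrogen-response genes rose in 5 of 8 and fell in 0 (6 and 0 adjusted over the list alone; adjusted p = 2.95e-05, and adjusted p = 0.243 with an estimated correlation). Greb1 was 4.45-fold and Igf1 1.87-fold higher. Lcn2 went from 0 to 44 counts, at least 20.3-fold higher, and Sprr2f, uncertain among its paralogs, from 3 to 50 (ratio 23.1, 7.46 to 116). In the knockout Lcn2, Sprr2f and C3 stayed at 9.30, 9.78 and 14.8 CPM, and Lcn2 was far higher in knockout epithelium. Epithelial and fibroblast RNA in muscle sums was not estimated, so these 3, Cxcl14 and matrix rises are not assigned to muscle. Cell cycle genes passed as a list (adjusted p = 0.0309, and adjusted p = 0.549 with an estimated correlation; 0.958 without control 2, 0.201 without knockout 1, 0.994 without knockout 2), though 0 of 15 passed singly with edgeR or with DESeq2, 0 adjusted over the list alone, and 1 was higher at an unadjusted p under 0.05. The replication genes Mcm5 (log2 1.25, adjusted p = 0.0760), Mcm3 (1.07, adjusted p = 0.261), Tyms (0.46, adjusted p = 0.292) and Hells (0.73, adjusted p = 0.317) were the nearest.

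The remaining lists did not pass in smooth muscle with all libraries in. Immediate early genes rose in 3 of 15 and fell in 0 (3 and 0 adjusted over the list alone; adjusted p = 0.113), with Ier3 5.47-fold and Dusp1 3.71-fold higher. That list passed without control 1 (1.94e-08) and without knockout 2 (2.00e-05). Stress and heat shock genes rose in 1 of 20 and fell in 2 (3 and 2 adjusted over the list alone; adjusted p = 0.444; 0.0109 without control 1 and 3.50e-05 without knockout 2), with Jun 2.37-fold higher and Mt2 4.54-fold lower. Implantation and decidualization genes rose in 2 of 13 and fell in 2 (4 and 4 adjusted over the list alone; adjusted p = 0.877), with Cebpb 2.71-fold higher and Itgb3 3.83-fold lower. The test placed this list above other genes while its median (−0.08) and mean (−0.47) log2 changes were below 0.

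The other large rises in smooth muscle were Thbs2 (43.0-fold, 0.728 ± 0.330 to 31.0 ± 1.05 CPM), Cxcl14 (22.5-fold), the retinol and alcohol dehydrogenase gene Adh1 (18.9-fold), Me3 (17.9-fold) and Fibin (15.7-fold), and Xdh, from 2 to 204 counts (ratio 141, 38.6 to 1175). Among the largest falls were Tac2, the neurokinin B gene, from 253 counts to 1 (ratio 183, 32.5 to 7240), Eya2 (16.5-fold), Rit2 (14.6-fold, 43.3 ± 2.05 to 2.48 ± 1.02 CPM), Nell1 (10.5-fold), Amhr2 (9.09-fold), Tnni2 (8.78-fold), Nrcam (8.45-fold), Tenm1 (8.11-fold) and Gpr83 (7.87-fold).

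**Figure D3:**
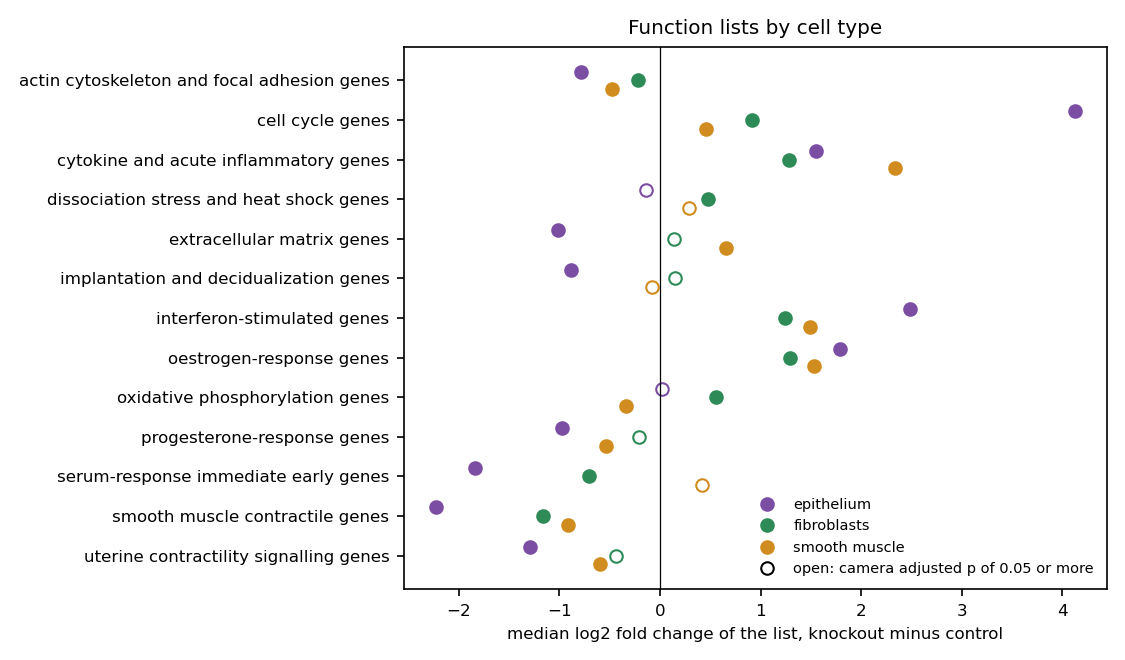
Median log2 change, knockout minus control, of the 13 function lists in epithelium, fibroblasts and smooth muscle, with open symbols for lists that camera did not call. Interferon-stimulated genes are higher and contractile genes lower in all 3 types, while oxidative phosphorylation genes are higher in fibroblasts and lower in smooth muscle.

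With the correlation between genes estimated from the libraries, camera called 0 of 13 lists in each of the 6 cell types. With 2 residual degrees of freedom this test could hardly call any list, so a list it did not call is not shown to be unchanged. At an unadjusted p under 0.05 that estimate gave 3 lists in smooth muscle, 1 in immune cells and 0 in the other types. fry, which asks whether the genes of a list move one way on balance, called 5 lists in epithelium, 3 in fibroblasts, 3 in smooth muscle, 4 in immune cells and 0 in perivascular and endothelial cells, where 2 and 0 had an unadjusted p under 0.05.

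Genotype effects were compared between cell types. Srf fell less in smooth muscle, so weaker effects there cannot be told from incomplete loss. Egr1 fell in epithelium and fibroblasts and was not called in smooth muscle (log2 −0.63, adjusted p = 0.208). The respiratory chain genes Uqcrq, Ndufa4 and Ndufb8 rose in fibroblasts and fell in smooth muscle, where all 3 lost the call with a block on replicate number and without cells high in markers of other types, and Uqcrq and Ndufb8 also with library totals. Matrix genes such as Dcn and Bgn rose in smooth muscle sums and fell in epithelial sums, neither assigned to those cells.

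The effect differed between fibroblasts and epithelium for 3329 of 18,155 genes (1630 higher and 1699 lower in fibroblasts), between smooth muscle and fibroblasts for 2870 of 16,679 (1322 and 1548), and between smooth muscle and epithelium for 2400 of 14,900 (1404 and 996). The first count was 955 without control 2, 1480 without control 1 and 1518 without knockout 2, and its split became 1903 and 1418 with median ratio size factors. The last was 1083 without knockout 2. Egr1 fell less in smooth muscle than in fibroblasts by 4.49 log2 units (interaction adjusted p = 6.77e-09), and its fall did not differ between fibroblasts and epithelium (0.13, adjusted p = 0.829). Csrp1 differed between fibroblasts and epithelium by 3.46 (adjusted p = 0.00158) and Uqcrq between smooth muscle and fibroblasts by −1.88. Epithelium and fibroblasts shared 1581 called genes of 14,172 tested in both, 751 higher in both, 552 lower in both and 278 opposite. Fibroblasts and smooth muscle shared 486 (165, 201 and 120) and epithelium and smooth muscle 373 (115, 151 and 107).

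Over all cells of a library, which mixes changes within types with changes in their shares, Srf was lower and Lcn2 and the neutrophil genes S100a8 and S100a9 were higher; the last pair, like Acta2 and Isg15 here, was chosen after its values were seen. Srf was lower by 2.33 log2 units (adjusted p = 0.00709), Lcn2 higher by 8.74 (adjusted p = 0.00502), S100a8 by 6.07 and S100a9 by 6.34, and Isg15 by 1.95 (adjusted p = 0.00519). Acta2 did not pass (−1.82, adjusted p = 0.0836). In total 3019 of 19,977 genes passed, 1706 higher and 1313 lower, and the count was 384 without control 2, 1550 without control 1 and 1641 without knockout 1. With the cell types weighted alike in each library 3868 passed.

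Immune and epithelial cells made up more of the knockout libraries, and fibroblasts less, without passing the test. Neutrophils and monocytes, the circulating phagocytes, were called more numerous, as were B cells, plasmacytoid dendritic cells and natural killer cells. A class the authors annotated as proliferating epithelium was found almost only in knockouts.

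Of the 8 broad types, 0 passed the edgeR test on cell numbers, and 2 had an unadjusted p under 0.05. Immune cells were 7.51% and 5.83% of cells in the controls and 27.7% and 15.7% in the knockouts (log2 1.70, adjusted p = 0.0596), and epithelial cells 7.11% and 4.94% against 21.8% and 12.9% (1.53, adjusted p = 0.0805). Fibroblasts were 58.7% and 70.2% against 37.0% and 49.4% (−0.58, adjusted p = 0.237) and smooth muscle 6.45% and 3.27% against 1.30% and 4.88% (−0.65, adjusted p = 0.755; without knockout 2 −1.90, adjusted p = 0.208 among the broad types and 0.0121 among the fine types). The exact permutation p was 0.33 for the first 3. Of 27 fine types, 11 passed. Proliferating epithelial cells numbered 0 and 1 in the controls and 168 and 266 in the knockouts (adjusted p = 3.16e-08), and the 0 of 9670 cells in control 1 allow up to 0.0381% (Clopper-Pearson, counting error only). Neutrophils numbered 25 and 15 against 552 and 215 (log2 4.41), monocytes 4 and 5 against 139 and 96 (4.80), and luminal epithelial cells 145 and 73 against 594 and 230 (2.09, adjusted p = 0.00883). Plasmacytoid dendritic cells (2.53), T and natural killer T cells (2.52), B cells (2.31), natural killer cells (1.92) and a conventional dendritic class (1.90) were more numerous too. Unclassified epithelial cells (−3.06) and fibroblasts in the G2 and M phases (−1.55, adjusted p = 0.0458) were fewer, while fibroblasts in S to G2 did not pass (1.31, adjusted p = 0.0711; 0.0227 without knockout 1). Some of these calls were lost without a library: luminal cells without control 1 (adjusted p = 0.109), control 2 (0.246) or knockout 1 (0.0609), B cells without knockout 1 (0.347) or knockout 2 (0.0630), and the dendritic class without control 1 (0.141) or control 2 (0.153). The fall of fibroblasts in G2 and M was lost without control 1 (0.396), control 2 (0.138) or knockout 2 (0.131), and also with a block on replicate number (0.0560) or as a share of cells outside the immune types (0.186). That block ended the luminal, B cell and dendritic calls too. Lost as well were the calls of natural killer cells (0.138) and T cells (0.0634) without control 2. Cell shares also follow tissue dissociation and droplet capture.

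**Figure D4:**
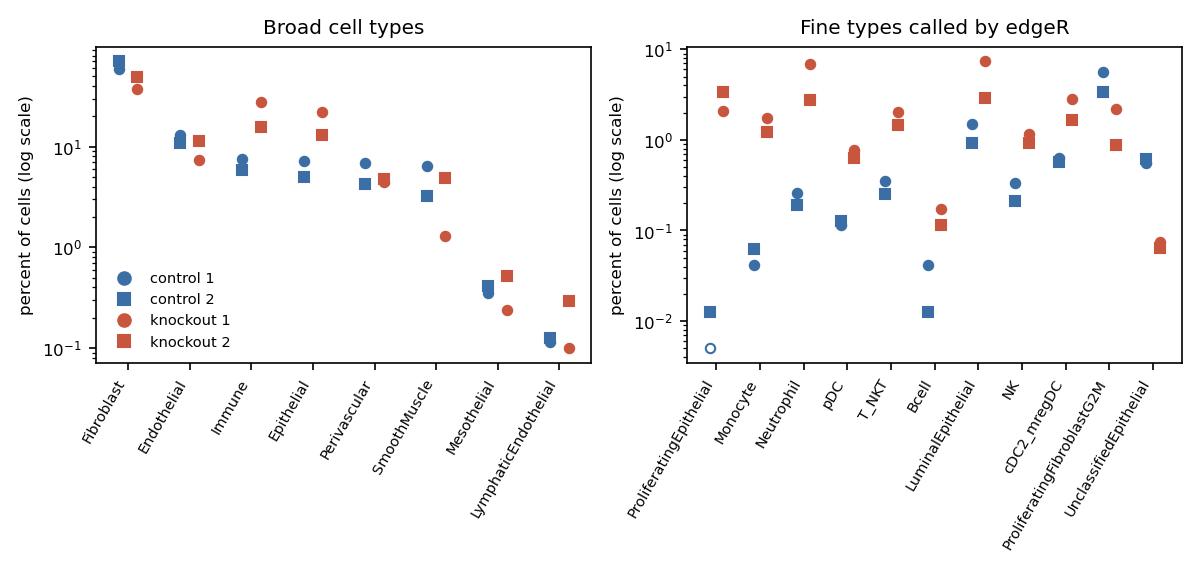
Percent of annotated cells per library in the broad types and in the fine types called by edgeR, on a log axis, with an open symbol at 0.005 for 0 cells. Neutrophils, monocytes and proliferating epithelial cells lie higher in both knockouts than in both controls.

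Mki67 and Top2a mark dividing cells. After thinning to 3000 UMIs the share of epithelial cells with a UMI of either was 31.1% and 37.8% in the controls and 31.6% and 30.8% in the knockouts (exact permutation p = 0.667). For Mki67 alone it was 0.929% and 1.68% against 6.87% and 14.0% (exact permutation p = 0.33), a measure added after the first was seen. Control glandular cells held 2165 and 2487 counts of Top2a but 18 and 10 of Mki67. In fibroblasts the share with either was 14.2% and 9.19% against 14.8% and 12.3% (exact permutation p = 0.667), and for Mki67 alone 11.9% and 7.65% against 8.89% and 6.55%, the other way (exact permutation p = 0.667). In smooth muscle, which hardly divides at this stage and serves as background, the share with either was 1.48% and 2.37% against 3.03% and 1.07%. Unthinned, the epithelial shares were 62.6%, 74.5%, 71.6% and 72.7%, at median depths of 18,568, 31,613, 29,292 and 38,320 UMIs, and those of smooth muscle 5.13%, 6.18%, 6.67% and 6.79%, at 10,374, 16,822, 9672 and 14,709 UMIs.

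Perivascular, endothelial and immune cells were tested in the same way. In perivascular cells the imprinted growth genes Mest, H19 and Dlk1 fell, and the phosphatase gene Ptpn5 rose. In endothelial cells the gap junction gene Gja5 and the BMP target Id1 rose. In immune cells Retnlg and Lcn2, made by neutrophils, rose and every tested cell cycle gene fell (adjusted p = 0.399 for the list with an estimated correlation), in sums whose mix of immune classes differed.

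Perivascular cells had 258 of 12,659 genes called (90 higher and 168 lower; 66 without control 2, 143 without control 1, 649 without knockout 2 and 1108 without knockout 1). Mest fell 29.3-fold (339 ± 117 to 11.7 ± 2.01 CPM, adjusted p = 0.000941), H19 15.9-fold and Dlk1 10.8-fold. Ptpn5 rose 28.6-fold and Slc15a3 5.80-fold. Camera called 8 of 13 lists (adjusted p = 0.523 to 0.643 with an estimated correlation). Cell cycle genes fell in 6 of 29 (21 adjusted over the list alone; adjusted p = 2.11e-17), actin genes in 5 of 29 (10; 1.13e-07), progesterone-response genes in 1 of 17 (7, and 1 higher; 0.000423) and contractile genes in 1 of 26 (7; 7.08e-05). Cytokine genes rose in 3 of 16 (9, and 2 lower; 8.94e-06), interferon-stimulated genes in 2 of 19 (9; 7.23e-06), oestrogen-response genes in 2 of 10 (4; 0.00147) and stress genes in 0 of 20 (0, and 0 with DESeq2, 3 at an unadjusted p under 0.05; 0.00524).

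Endothelial cells had 76 of 13,961 genes called (42 higher and 34 lower), 2 without knockout 1, 30 without knockout 2, 110 without control 2 and 1481 without control 1. Gja5 rose 3.23-fold, Serpine2 2.80-fold and Id1 2.79-fold, and Aoc3 fell 5.11-fold and Fam13a 4.96-fold, calls lost without knockout 1 (adjusted p = 0.0520 to 0.0545). Fam155a fell 5.83-fold (41.1 ± 3.49 to 7.03 ± 0.192 CPM, adjusted p = 0.00361) and kept its call. Camera called 6 lists (adjusted p = 0.647 to 0.817 with an estimated correlation). Cell cycle genes were 0 of 29 higher singly by edgeR, 14 by DESeq2, 18 at an unadjusted p under 0.05 and 16 adjusted over the list alone (adjusted p = 1.71e-10). Cytokine genes rose in 1 of 20 (4 adjusted over the list alone; adjusted p = 0.00320), interferon-stimulated genes in 1 of 20 (5; 0.00277), and contractile genes fell in 1 of 20 (9, and 1 higher; 0.00102). Stress genes (0 of 20 by edgeR, 4 adjusted over the list alone, 4 by DESeq2, 5 higher and 1 lower at an unadjusted p under 0.05; 0.0484) and oestrogen-response genes (0 of 11 by edgeR, 4 higher and 1 lower adjusted over the list alone, 3 and 1 by DESeq2, 5 and 1 at an unadjusted p under 0.05; 0.0112) were called higher as lists.

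Immune cells had 1771 of 13,240 genes called (944 higher and 827 lower), 929 without control 2, 1072 without knockout 1, 1420 without knockout 2 and 1705 without control 1. With library totals the median log2 change became −0.16 and the split 691 higher and 1285 lower. Retnlg rose 282-fold (1.12 ± 0.145 to 319 ± 6.95 CPM, adjusted p = 0.000164). Lcn2 rose 365-fold (knockouts 255 ± 261 CPM) and Wfdc21 from 3 counts to 4706 (ratio 591, 202 to 2865), both lost without control 2 (0.0684 and 0.0563). Chl1 fell 9.59-fold, Tmsb15a 7.78-fold and Klra4, which has close paralogs, 6.60-fold. Neutrophil markers rose in 8 of 8 (adjusted p = 7.58e-11, and adjusted p = 0.60 with an estimated correlation). Cell cycle genes fell in 29 of 29 (29 adjusted over the list alone; adjusted p = 3.44e-24, and adjusted p = 0.399 with an estimated correlation) and interferon-stimulated genes rose in 19 of 20 (20; 5.67e-18, and adjusted p = 0.332 with an estimated correlation). Proliferating natural killer cells were 134 of 726 and 81 of 462 immune cells in the controls. In the knockouts they were 61 of 2235 and 52 of 1232. Their share of all cells did not pass the test (log2 −0.76, adjusted p = 0.292). The fall of cell cycle genes therefore cannot be told apart from a changed mix of immune classes. Cytokine genes rose in 9 of 22 and fell in 1 (13 and 1 over the list alone, adjusted p = 1.27e-05, and adjusted p = 0.522 with an estimated correlation). Immediate early genes rose in 3 of 19 (5, adjusted p = 0.00631, and adjusted p = 0.648 with an estimated correlation). Contractile genes fell in 3 of 20 (19, adjusted p = 3.29e-07, and adjusted p = 0.522 with an estimated correlation). Srf was not called in endothelial or immune cells, yet contractile genes fell in the sums of both. Smooth muscle markers also fell in failing barcodes of few genes (1441 and 1137 CPM in the controls, 220 and 505 in the knockouts). Muscle RNA carried into the perivascular, endothelial and immune sums was not estimated, so these falls are not assigned to those cells.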

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

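The supply test for contractile genes with its marker choice, the tests within glandular and stromal cells, and the comparison of barcodes left out on other grounds were chosen only after results were seen; the immune supply test and the tests of gene and list changes were set before.

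Genes that responded in opposite directions in 2 cell types were the first surprise, among 3329 genes whose genotype effect differed between fibroblasts and epithelium, 2870 between smooth muscle and fibroblasts and 2400 between smooth muscle and epithelium. Between fibroblasts and epithelium the differences in log2 change were −7.72 for Egfl6, −4.52 for Fst, −4.28 for Nt5e, 2.35 for Cacna1c, 3.68 for Thbs1 and 8.48 for Thsd7b. Egfl6 fell by 1.53 in fibroblasts while it rose by 6.10 in epithelium, and Thsd7b rose by 2.43 and fell by 6.19. For Cacna1c the epithelial fall was lost without cells high in markers of other types (log2 −0.03), so RNA of other cells might account for it.

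Between smooth muscle and fibroblasts the differences were −4.68 for Chchd10, −3.87 for Tenm1, −2.96 for Mt2, −1.88 for Uqcrq, −1.35 for Ndufa4, −1.26 for Ndufb8, 1.96 for Cxcl12, 2.86 for Dcn and 1.87 for Igf1. Chchd10, Uqcrq, Ndufa4 and Ndufb8 encode mitochondrial proteins. They rose in fibroblasts and fell in smooth muscle, where Ndufb8 and Uqcrq lost the call with library totals and the last 3 lost it with a block on replicate number and without cells high in markers of other types. Scaling could explain part of the smooth muscle side: with library totals 4 of 58 called named genes lost their call.

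Between smooth muscle and epithelium the differences were 6.51 for Adh1, 3.54 for Bgn, 2.91 for Cxcl12, 4.04 for Dcn, 1.83 for Esr1, 3.68 for Igf1, 2.19 for Jun, 4.42 for Thbs1, 8.90 for Thsd7b, −1.37 for Hspb1, −3.08 for Nt5e and −6.53 for Tenm1. The 12.87 of Slc24a4 rests on 1, 0, 4 and 48 counts in smooth muscle and is a fitted value of a gene near 0. Dcn, Bgn and Igf1 are stromal genes, which fell in epithelium together with stromal markers.

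The fall of smooth muscle contractile genes in epithelium was weighed against RNA or cells of other types among the epithelial droplets. For the 12 members under 50 CPM in the controls, other cell types could supply a median of 120% of the difference (13.4% to 280%). The markers behind that estimate include 3 of these same genes, Myh11, Cnn1 and Des, so the value restates part of the fall. Carried-over RNA and a loss in epithelial cells cannot be told apart for these 12. For the 3 members of at least 50 CPM the median was 1.91% (0.836% to 6.78%), so carried-over RNA is excluded as the main source for these 3. A first version of this estimate kept too few smooth muscle markers and gave an impossible share; the full marker lists replaced it after that was seen. The median log2 change of the 15 fallen members was −2.71 in glandular cells and −2.73 in all epithelium. As 12 are undecided, this cannot exclude a changed subtype mix.

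The rise of interferon-stimulated genes in epithelium and fibroblasts went with more immune cells in the knockout libraries, so immune RNA in other droplets might have raised it. Immune cells could supply a median of 0.293% of the difference in epithelium (20 members) and 0.655% in fibroblasts (16 members), and this explanation is excluded. A changed cell mix is excluded too: the median log2 change was 2.84 in glandular cells against 2.48 in all epithelium, and 1.60 in stromal fibroblasts against 1.48 in all fibroblasts. The immune sums showed the rise themselves, though their mix of immune classes differed between the genotypes. Few members were called singly in endothelial or perivascular cells, though camera called the list in both at the preset correlation. A hypothesis is that signals from the immune cells induced these genes in their neighbours. Mice without the interferon receptor, not analysed here, would test it.

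Genotype cannot be told apart from what came with it. Cre was present in knockouts only, in the Pgr locus, so the changed Pgr locus or Cre itself could also act. The 2.08-fold rise of Pgr in epithelium, 1.05 on the log2 scale, could come from either. Neither littermate status nor processing day is given in the sources used here.

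Barcodes that the authors' annotation failed held more of some markers in the knockouts, most of them immune. Among those of few genes (649, 660, 883 and 435 barcodes) the knockout to control ratio was 2.47 for dendritic markers and 2.37 for macrophage and monocyte and 1.73 for natural killer and T cell markers, while neutrophil and B cell markers overlapped between the genotypes. Among the rest (2260, 2357, 1587 and 1709 barcodes) it was 38.8 for neutrophil markers, 5.13 for macrophage and monocyte, 4.08 for B cell, 3.06 for dendritic and 2.40 for natural killer and T cell markers, and also 1.88 for luminal epithelium and 1.53 for glial markers, which are not immune.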

How the results depend on the processing

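The fits in glandular, luminal, stromal or basal cells alone, the fit without proliferating and unclassified epithelium and the share with Mki67 alone were chosen only after results were seen, as was the choice to show fine cell types only where edgeR called them; all other alternatives were planned. Except where said, the cause of a change was not tested.

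The choice of scaling mattered little for the named genes, most of them chosen for large changes or small p. Over all genes, library totals moved the split of calls from 2102 higher and 2008 lower to 2922 and 1531 in epithelium. In immune cells it went from 944 and 827 to 691 and 1285. Of 230 results on named genes, 228 stayed the same with median ratio size factors and 226 with library totals. With DESeq2 221 stayed the same, 5 lost the call and 4 gained one. Without an expression filter 221 stayed the same and 9 gained a call. Limits on UMIs and mitochondrial share left 226 the same, and leaving out cells high in markers of another main type left 214 the same, with 13 calls lost, 12 of them in smooth muscle. Equal cell numbers thinned to 3000 UMIs kept 188 of 198.

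Leaving out a library cost more, and in these fits the lone library of a genotype is assumed to vary like the other genotype. Of the 230 results 200 stayed the same without control 1, 178 without control 2 and 209 without knockout 1, and 209 of 229 without knockout 2. Of the 51 calls lost without control 2, 45 lay in smooth muscle. Each fit has 1 library against 2 and less power, which cannot alone explain the uneven losses. For Acta2 the log2 change stayed put (−1.16 without control 2, −1.15 with all).

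The number of changed genes moved with the library left out: from 2 to 1481 in endothelial cells, 2003 to 3748 in epithelium, 1340 to 5534 in fibroblasts, 929 to 1705 in immune cells, 66 to 1108 in perivascular cells, 34 to 1153 in smooth muscle and 384 to 3668 over all cells. The genes whose genotype effect differed ranged from 955 to 2531 between fibroblasts and epithelium and from 1083 to 2084 between smooth muscle and epithelium.

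Other settings moved these counts too. Without an expression filter they were 1896 in endothelial cells, 3088 in immune cells, 1377 in perivascular cells and 1985 in smooth muscle. DESeq2 gave 816 in endothelial cells, 640 in smooth muscle and 4713 over all cells. Leaving out cells high in markers of other types gave 160 in endothelial cells and 477 in smooth muscle. Limits on UMIs and mitochondrial share gave 2718 in epithelium and 167 in perivascular cells. Equal cell numbers thinned to 3000 UMIs gave 1400 in epithelium, 767 in immune cells and 338 in smooth muscle, where fewer UMIs by construction leave fewer genes to test. Glandular cells alone gave 2608 and basal fibroblasts alone 160.

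A block on replicate number, which pairs libraries that the labels do not pair, gave 217 changed genes in endothelial cells, 170 in perivascular cells, 358 in smooth muscle and 4783 over all cells. With this block 217 of 230 named gene results stayed the same, and the 13 calls lost were all in smooth muscle. The pairing made cell numbers pass for fibroblasts (log2 −0.59, adjusted p = 0.0103) and immune cells (1.66, adjusted p = 0.0364). It ended the calls of luminal epithelial cells, B cells, the conventional dendritic class and fibroblasts in G2 and M (each at adjusted p = 0.0560). It also turned the direction of implantation and decidualization genes in smooth muscle (adjusted p = 0.956).

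For gene lists the correlation between genes mattered most. With it estimated, 0 lists were called in each of the 6 cell types. Of 39 list results 30 lost their call, but the estimate rests on 2 residual degrees of freedom and cannot show a list unchanged. The count of called lists in endothelial cells ranged from 3 to 8 with a library left out. Of the 39 list results 39 stayed the same with median ratio size factors, 36 with library totals and 35 without an expression filter, and 34, 34, 34 and 32 without control 1, control 2, knockout 1 and knockout 2.

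Lists that changed direction were mostly ones that did not pass. Stress and heat shock genes in epithelium turned without an expression filter (adjusted p = 0.936), and implantation and decidualization genes in smooth muscle turned with library totals (0.816) and without a filter (0.885). Uterine contractility signalling genes turned in luminal cells alone (0.157), where extracellular matrix (0.12) and implantation genes (0.907) lost their calls; the latter lost it in glandular cells alone too (0.0822). In basal fibroblasts alone cell cycle genes (0.0509), extracellular matrix genes (0.00912) and immediate early genes (0.453) turned.

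With single libraries left out the adjusted p of these lists ranged from 0.250 to 0.904 for stress and 0.104 to 0.960 for oxidative phosphorylation genes in epithelium, and from 0.0775 to 0.790 for extracellular matrix genes in fibroblasts. In smooth muscle it ranged from 0.0162 to 0.994 for cell cycle, 3.50e-05 to 0.866 for stress, 0.254 to 0.972 for implantation and 1.94e-08 to 0.958 for immediate early genes, so nothing firm can be said of those 4 lists there.

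Luminal cells alone reversed 8 epithelial genes: Atf3 (log2 0.94), Chrm3 (2.29), Esr1 (0.43), Hspb1 (−0.30), Il6st (0.46), Itga5 (0.80), Kcnma1 (1.31) and Lif (3.14). The difference between luminal and glandular cells was not tested, yet the epithelial falls of Lif, Chrm3 and Esr1 may be those of glands, with more luminal cells in the knockouts. Of 59 results 43 stayed the same in luminal cells, and of 57 results 50 in glandular cells. Without proliferating and unclassified epithelium 61 of 63 stayed the same.

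Basal fibroblasts alone reversed Bmper (1.09), Btg2 (0.14), Ccl8 (−0.32), Ccne1 (−1.65), Cxcl14 (−0.032), Hells (−0.68), Mcm3 (−0.93) and Mcm6 (−0.88). All 65 results on single genes stayed the same in stromal fibroblasts, where the call of cell cycle genes as a list was lost (adjusted p = 0.0867). Only 97 basal cells came from knockout 1.

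The other genes that changed sign were ones that edgeR had not called. Srf in endothelial cells was 0.022 with limits on UMIs and 0.031 without cells high in other markers, and ranged from −0.28 to 0.17 with a library left out; in immune cells it ranged from −0.16 to 0.043. Pgr in immune cells was 0.30 without cells high in other markers. Mkl2 in epithelium was 0.065 after thinning. In smooth muscle Mkl1 was −0.028 and Mkl2 0.10 after thinning, and with a library left out Mkl1 ranged from −0.080 to 0.39, Mkl2 from −0.66 to 0.10, Hells from −0.28 to 0.99 and Mcm3 from −0.65 to 1.42.

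For cell numbers, the share of all cells ties types together: when immune cells rise, others fall by construction. Outside the immune types epithelial cells passed (log2 1.81, adjusted p = 0.0193), and the fall of fibroblasts in G2 and M lost its call (−1.25, adjusted p = 0.186). With limits on UMIs immune cells passed (1.80, adjusted p = 0.0464). Mesothelial cells turned to 0.16 with those limits and 0.21 outside the immune types. With a library left out lymphatic endothelial cells ranged from −0.26 to 1.28 (called without knockout 1, adjusted p = 0.0253), mesothelial cells from −0.70 to 0.45, perivascular cells from −0.57 to 0.12 and smooth muscle from −1.90 without knockout 2 (adjusted p = 0.208 among the broad types, but called at 0.0121 among the fine types) to 0.0056 without knockout 1.

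For shares of cells with a UMI, the difference in Srf in endothelial cells turned to 2.02 points unthinned, where depth differs between libraries. The share of epithelial cells with Mki67 or Top2a differed by 3.56 points unthinned and 1.80 at 1500 UMIs, and by 9.15 for Mki67 alone. With a library left out it ranged from −6.60 to 0.102 points. In fibroblasts Mki67 alone gave −2.05 points, and the range for either gene was −0.660 to 4.32. In smooth muscle the difference was −0.119 at 1500 UMIs and ranged from −0.859 to 1.10.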

Other observations

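The Top2a tests below were chosen only after the counts of that gene were seen, except the neighbour test, whose prediction was written down before, and whose verdict was corrected to that prediction after its value was seen.

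In control glandular cells Top2a had 2165 and 2487 counts, while Mki67, which dividing cells make together with it, had 18 and 10. Free RNA of dividing cells is excluded, since the ratio of Top2a to Mki67 was at least 72.3 times that of proliferating fibroblasts in either control. Transcripts of a neighbouring gene counted as Top2a cannot be told apart from Top2a itself: the highest glandular level among the neighbours that were not ruled out was 18.8 CPM (Tns4), against 207 CPM of Top2a. A hypothesis is that glandular cells hold Top2a transcripts without dividing, and reads over the gene body, not used here, could test it. For shares of dividing epithelial cells Mki67 alone is the safer measure, and it differed by 9.15 points between the genotypes.

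The perivascular falls of Mest, H19 and Dlk1, all imprinted genes of growing tissue, went with a fall of cell cycle genes there (6 of 29 singly, and the list call was lost with an estimated correlation, adjusted p = 0.523). The share of perivascular cells with Mki67 or Top2a was 19.6% and 19.9% in the controls and 9.48% and 5.69% in the knockouts. All 3 calls held in each alternative in which they were tested, and the count of perivascular calls ranged from 66 to 1108 with single libraries left out.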
